A study of Mus musculus with 42 samples.

How the data were processed

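RNA of splenic B cells from 3 mice per group was sequenced after 4 or 24 h of culture, in 42 libraries. The values are log2 CPM (read counts scaled to a common library total), made and normalised by the authors before they were deposited. The submitters' notes name FastQC 0.11.5, cutadapt 1.8.3, STAR 2.6.0c, featureCounts, Subread 1.6.2 and limma, with the mouse genome build mm10, without the role or order of each. The labels describe Smart-Seq v4 cDNA and Nextera libraries read on a NextSeq 2000. The filter that left 11325 genes and the normalisation steps are not stated. The deposited log2 values have nearly the same distribution in every library (the sorted values differ by a median of 0.023 across libraries). Their means over the 14 groups are equal for mouse 1, 2 and 3 within 0.00064 for every gene, which is what removal of a mouse effect over all 42 libraries leaves behind.

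From there, genes with a mean log2 value of 0 or more over the libraries of a fit were tested, 10183 at 4 h, 10236 at 24 h and 10187 over all libraries. One mean per group was fitted with limma 3.58.1 in R 4.3.3 (moderated test with the trend and robust settings, two-sided), using all groups of a time point, or all 14 groups for comparisons across time. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and rose, fell and changed are used of such genes. No values were rescaled and no libraries were left out. The comparisons, tests, alternatives, gene lists and the rule for naming genes were chosen before the data were examined, except where stated.

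The numbers of the mice pair libraries across groups. Residuals of libraries with the same number had a mean correlation across genes of -0.06 over 135 pairs of libraries at 4 h and 0.03 over 18 at 24 h. Equal means of the mice over all 42 libraries pull these correlations down, so they do not show whether the mice differed. Within a time point the means of mouse 1, 2 and 3 are not made equal, so part of a mouse effect may remain there. The test was fitted without the number, as planned. A paired fit with mouse number as a replicate block is an alternative, in which the count for IL-12 left alone against blocked is 78 in place of 130, and the 24 h counts are 922 in place of 747 for IFNγ, 60 in place of 42 for IL-12 and 80 in place of 53 for their interaction.

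Alternatives repeated every comparison with quantile normalization, without the filter, without the trend and robust settings, with the compared groups alone, with the replicate block, at an adjusted p of 0.01, with a log2 difference of 1 or more, and without each compared library in turn. Chosen after seeing the data were fits without 1 of 2 groups (IL-12 20 with IFNγ blocked, and IL-12 left alone) and with a smooth trend on transcript length removed from each library. Each count was set beside those from other splits of the same libraries. The overlap of the 24 h comparisons was set beside 100 simulated draws in which unchanged groups share the controls. Principal components were computed on the log2 values of all libraries. The depth per library is unknown, so precision rests on the spread between libraries. If a mouse effect was removed before deposit, that spread leaves out part of the differences between mice. The SDs, standard errors and p-values may then be too small.

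Gene lists were the interferon-induced GTPases, interferon signalling, type I interferon genes, MHC class I and class II presentation, type 1 lymphocyte genes, genes of T-bet positive B cells, B cell identity, activation, germinal centre, plasma cell, unfolded protein response, NF-kappaB targets, cytokines and chemokines, trafficking of resting B cells, cell death, S phase, mitosis, glycolysis, ribosome biogenesis, and markers of T cells, NK cells, myeloid, dendritic and erythroid cells. Each list with 5 or more tested genes was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Beside a camera call that an estimated correlation ended, that p is given, and each other camera call printed also passed with it.

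Genes are named by a rule: fixed genes of the IL-12, IFNγ and B cell programmes, the 10 that rose and the 10 that fell most among called and well expressed genes, the 4 members of each list with the lowest p, and all called genes where 5 or fewer passed. A few genes under this rule are not reported here. Symbols were matched to current names (766 were older ones), and positions and transcript lengths came from GENCODE M21, with a length for 11238 genes. In a self-test with 50 genes shifted by each of 4 sizes, the 4 h test with 3 against 3 libraries recovered 30, 78, 98 and 100% of log2 shifts of 0.25, 0.5, 1 and 2, and the 24 h interaction test 2, 36, 78 and 100%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.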

Results

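The data are RNA sequencing profiles of B cells purified from the spleens of C57BL/6 mice and cultured with LPS, a bacterial product that activates B cells through TLR4. The cultures differed in time and in 2 cytokines, IL-12 and IFNγ, each of which was added or held off with a blocking antibody. There are 42 libraries in 14 groups, with 3 libraries per group from mice numbered 1 to 3. At 4 h, IL-12 was blocked or given at 20, 200 or 2000 pg/mL, each with IFNγ blocked or given at 0.5 ng/mL. Another 2 groups at 4 h received IFNγ at 3 ng/mL with IL-12 either blocked or left alone, that is, neither added nor blocked. At 24 h there are 4 groups, with IL-12 blocked or at 20 pg/mL and IFNγ blocked or at 0.5 ng/mL. The question put by the series text is how much each cytokine adds by itself and next to the other. Each library lists log2 CPM (read counts scaled to a common library total) for 11325 genes, and the CPM add up to between 992211 and 1001971 per library. The number of reads behind a library is unknown, so no counting error or floor is given. A log2 difference stands with its standard error from limma and compares 3 libraries with 3, while a level is a mean log2 CPM with its SD over 3 libraries. Genome positions are on GRCm38 (mm10), and each gene given with a position is annotated as protein coding.

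Culture time separated the libraries first. On the first principal component (80.3% of the variance) the 24 h libraries lay between -89.7 and -83.6 and the 4 h libraries between 25.2 and 43.8. On the second (9.4%), the 4 h libraries with IFNγ blocked lay between 23.3 and 28.2 and those with IFNγ between -20 and -14.5.

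IFNγ at 0.5 ng/mL for 4 h was compared with blocked IFNγ, with IL-12 blocked in both groups. No group had IFNγ neither added nor blocked. Added IFNγ therefore cannot be told apart from the lack of the blocking antibody or from IFNγ made in the culture. This holds for every comparison of added with blocked IFNγ here. Tbx21 (chromosome 11, 97098071 to 97115331), which encodes the transcription factor T-bet, rose 111-fold (6.80 ± 0.17, adjusted p = 3.4e-18). Genes of the classical IFNγ response rose with it, among them the guanylate-binding protein gene Gbp2 by 6.14 ± 0.09 and the immunity-related GTPase gene Iigp1 (chromosome 18, 60376027 to 60392634) by 6.66 ± 0.39. The transcription factor genes Irf1 (chromosome 11, 53770014 to 53778374) and Irf8 rose by 3.05 ± 0.17 and 1.67 ± 0.04, and the feedback inhibitor Socs1 (chromosome 16, 10782240 to 10785536) by 3.71 ± 0.29. The IL-12 receptor chain gene Il12rb1 (chromosome 8, 70808449 to 70821424) rose by 4.10 ± 0.42, from a level of -1.51 ± 1.14 to 2.59 ± 0.19. Il12rb2 (chromosome 6, 67291318 to 67376188), the other chain, rose by 1.03 ± 0.24. The gene for IFNγ itself, Ifng (chromosome 10, 118441046 to 118445892), did not pass (0.40 ± 0.55, adjusted p = 0.63). Of 10183 genes tested, 1531 rose and 1733 fell, 190 and 113 of them by a log2 difference of 1 or more.

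Other large rises were those of the serpin genes Serpina3g (5.90 ± 0.35) and Serpina3f (6.02 ± 0.44), the fatty acid receptor gene Ffar2 (4.61 ± 0.29), Gbp7 (5.13 ± 0.37) and Tgtp1 (5.29 ± 0.40). The chemokine gene Cxcl9 (chromosome 5, 92321347 to 92328079), whose control level is near the lowest of the 4 h libraries (-3.93 ± 1.61), reached 3.51 ± 0.11 (adjusted p = 1.6e-09). The related Cxcl10 (chromosome 5, 92346638 to 92348889) rose by 1.75 ± 0.38. Among surface molecules, the death receptor gene Fas rose by 2.31 ± 0.09, Cd274 (chromosome 19, 29367455 to 29388095), which encodes PD-L1, by 1.34 ± 0.12, and the costimulatory gene Cd86 by 0.69 ± 0.06 and Cd200, the ligand of an inhibitory receptor, by 1.93 ± 0.09. Prdm1 (chromosome 10, 44437177 to 44528501), the regulator of plasma cell differentiation, rose by 0.48 ± 0.14. Large falls were those of the ethanolamine kinase gene Etnk2 (-2.27 ± 0.17), the basement membrane gene Nid1 (-2.17 ± 0.10), Tnfrsf19 (-1.94 ± 0.10), the sodium channel gene Scn4a (-1.88 ± 0.13) and the lysosome gene Lyst (-1.55 ± 0.08). The genes Stat4 (chromosome 1, 51987148 to 52107189) (0.07 ± 0.07), Cxcr3 (chromosome X, 101731535 to 101734269) (-0.07 ± 0.19), Bcl6 (chromosome 16, 23965052 to 23988852) (0.10 ± 0.08), Myc (0.11 ± 0.06), Xbp1 (0.04 ± 0.06), Pax5 (0.15 ± 0.11) and Irf4 (-0.10 ± 0.05) did not pass.

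The fixed gene lists group these changes. Of the interferon-induced GTPases, 17 rose, 0 fell and 0 did not pass (17 and 0 adjusted over the list alone, camera adjusted p = 1.2e-24 up, adjusted p = 0.059 with an estimated correlation). Of the MHC class I presentation genes, 16 rose, 0 fell and 0 did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 1.9e-19 up), with Tap2 at 1.45 ± 0.05 and the immunoproteasome gene Psmb9 at 2.92 ± 0.14. Of interferon signalling genes, 11 rose, 4 fell and 4 did not pass (11 and 4 adjusted over the list alone, camera adjusted p = 1.1e-05 up, adjusted p = 0.15 with an estimated correlation). Of MHC class II presentation genes, 1 rose, 6 fell and 4 did not pass (1 and 6 adjusted over the list alone, camera adjusted p = 0.0072 down, adjusted p = 0.29 with an estimated correlation), with falls of H2-Eb1 (-0.54 ± 0.04) and H2-Aa (-0.29 ± 0.04). Among genes best known from type I interferon, 2 rose, 13 fell and 11 did not pass (2 and 14 adjusted over the list alone, camera adjusted p = 0.015 down, adjusted p = 0.65 with an estimated correlation). Their antiviral members Ifit3 (chromosome 19, 34583531 to 34588731), Rsad2 and Ddx58 changed by -2.40 ± 0.52, -1.62 ± 0.43 and -1.44 ± 0.30, while the nucleic acid sensor gene Zbp1 rose by 2.91 ± 0.37. Of B cell identity genes, 3 rose, 13 fell and 4 did not pass (3 and 13 adjusted over the list alone, camera adjusted p = 4.9e-06 down, adjusted p = 0.16 with an estimated correlation), with falls of the IgM receptor gene Faim3 (-1.51 ± 0.06), the complement receptor gene Cr2 (-0.99 ± 0.05) and the antigen receptor gene Cd79a (-0.88 ± 0.05) and a rise of Bach2 (1.03 ± 0.08). Of B cell activation genes, 10 rose, 5 fell and 3 did not pass (11 and 5 adjusted over the list alone, camera adjusted p = 0.0026 up, adjusted p = 0.15 with an estimated correlation). Of type 1 lymphocyte genes, 8 rose, 1 fell and 15 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 0.0017 up, adjusted p = 0.29 with an estimated correlation), with the IL-18 receptor chain gene Il18rap (chromosome 1, 40515362 to 40551705) at 2.02 ± 0.15. Of genes of T-bet positive B cells, 5 rose, 1 fell and 8 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.0062 up, adjusted p = 0.098 with an estimated correlation).

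The remaining lists did not pass camera. Of NF-kappaB targets, 5 rose, 10 fell and 6 did not pass (5 and 10 adjusted over the list alone, camera adjusted p = 0.37 down). Of glycolysis genes, 4 rose, 8 fell and 7 did not pass (4 and 9 adjusted over the list alone, camera adjusted p = 0.37 down). Of cytokine and chemokine genes, 8 rose, 4 fell and 8 did not pass (8 and 4 adjusted over the list alone, camera adjusted p = 0.1 up). Of cell death genes, 8 rose, 3 fell and 8 did not pass (8 and 3 adjusted over the list alone, camera adjusted p = 0.12 up). Of germinal centre genes, 3 rose, 3 fell and 7 did not pass (4 and 3 adjusted over the list alone, camera adjusted p = 0.51 up). Of trafficking genes of resting B cells, 3 rose, 7 fell and 5 did not pass (3 and 8 adjusted over the list alone, camera adjusted p = 0.1 down). Of plasma cell genes, 5 rose, 3 fell and 9 did not pass (5 and 3 adjusted over the list alone, camera adjusted p = 0.34 up). Of unfolded protein response genes, 4 rose, 7 fell and 13 did not pass (5 and 8 adjusted over the list alone, camera adjusted p = 0.91 down).

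For the cell cycle, 6 rose, 2 fell and 16 did not pass (6 and 2 adjusted over the list alone, camera adjusted p = 0.16 up) in the S phase list and 1 rose, 0 fell and 17 did not pass (1 and 0 adjusted over the list alone, camera adjusted p = 0.33 up) in the mitosis list. Of ribosome biogenesis genes, 6 rose, 0 fell and 14 did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 0.25 up). For markers of other cells, 1 rose, 0 fell and 12 did not pass (1 and 0 adjusted over the list alone, camera adjusted p = 0.71 up) among T cell genes and 1 rose, 0 fell and 9 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.22 up) among NK cell genes. Of myeloid genes, 1 rose, 0 fell and 9 did not pass (1 and 0 adjusted over the list alone, camera adjusted p = 0.91 up), and of dendritic cell genes, 1 rose, 3 fell and 3 did not pass (1 and 3 adjusted over the list alone, camera adjusted p = 0.17 down). The single erythroid gene listed in the files, Car2, did not pass (0.02 ± 0.08). Constant-region genes of the antibody heavy chains, among them the fixed gene Ighg2c, were not analysed here.

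A higher dose of IFNγ, 3 ng/mL, was compared with blocked IFNγ at 4 h, again with IL-12 blocked. Tbx21 rose by 7.29 ± 0.17, Gbp2 by 6.48 ± 0.09, Iigp1 by 7.28 ± 0.39, Socs1 by 4.16 ± 0.29, Irf1 by 3.30 ± 0.17, Il12rb1 by 4.41 ± 0.42 and Cxcl10 by 2.27 ± 0.38. Prdm1 rose by 1.02 ± 0.14 and Cd274 by 1.63 ± 0.12. The sialyltransferase gene St6gal1 (-1.65 ± 0.08), the sphingomyelin synthase gene Sgms1 (-1.70 ± 0.13), Nid1 (-2.49 ± 0.10), Etnk2 (-2.41 ± 0.17) and Faim3 (-1.58 ± 0.06) fell. Ifng did not pass (0.67 ± 0.55). In total 1446 genes rose and 1862 fell, 228 and 144 of them by a log2 difference of 1 or more. Of the GTPases, 17 rose, 0 fell and 0 did not pass (17 and 0 adjusted over the list alone, camera adjusted p = 1.2e-25 up). Of genes of T-bet positive B cells, 6 rose, 1 fell and 7 did not pass (7 and 1 adjusted over the list alone, camera adjusted p = 0.00021 up). Of type I interferon genes, 2 rose, 14 fell and 10 did not pass (2 and 15 adjusted over the list alone, camera adjusted p = 0.032 down, adjusted p = 0.77 with an estimated correlation).

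The groups with 3 and 0.5 ng/mL of IFNγ were also compared directly. The higher dose gave higher Smad1, a transducer of BMP signals (0.55 ± 0.08, adjusted p = 0.00033), Irf8 (0.24 ± 0.04), the coactivator gene Mkl1 (0.56 ± 0.09), the transcription factor gene Zeb2 (0.38 ± 0.07) and the adhesion molecule gene Icam1 (0.26 ± 0.05), and lower Emc9 (-0.57 ± 0.10). In total 100 genes rose and 49 fell. Those that fell had a median transcript length of 859 nt and those that rose 1471 nt, against 1334 nt for all tested. Spearman's rho of length and log2 difference was 0.15, so a length bias between libraries stays open for these calls. Tbx21 (0.49 ± 0.17, adjusted p = 0.15), Socs1 (0.46 ± 0.29) and Il12rb1 (0.31 ± 0.42) did not pass. Of interferon signalling genes, 3 rose, 0 fell and 16 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.0023 up, adjusted p = 0.44 with an estimated correlation). Of activation genes, 3 rose, 0 fell and 15 did not pass (3 and 0 adjusted over the list alone, camera adjusted p = 0.0042 up, adjusted p = 0.19 with an estimated correlation), and of NF-kappaB targets, 2 rose, 1 fell and 18 did not pass (3 and 2 adjusted over the list alone, camera adjusted p = 0.026 up, adjusted p = 0.19 with an estimated correlation). The total of 149 became 21, 94 and 34 without replicates 1, 2 and 3 of the 0.5 ng/mL group, and 26 and 31 without replicates 2 and 3 of the 3 ng/mL group. With only these 6 libraries fitted it was 707, and Tbx21 (adjusted p = 0.0082) and Socs1 (9.5e-06) were then among them.

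IL-12 alone, with IFNγ blocked, was tested at 3 doses at 4 h, and its clearest effect was on Ifng. The level of Ifng was -1.22 ± 1.46 with both cytokines blocked, 2.86 ± 0.48 with 20 pg/mL of IL-12, 4.49 ± 0.20 with 200 and 4.90 ± 0.27 with 2000 pg/mL. The log2 differences were 4.09 ± 0.55 (adjusted p = 0.0037), 5.72 ± 0.55 (1.6e-05) and 6.13 ± 0.55 (4.9e-06), and each of the 9 libraries with IL-12 lay above the 3 controls, which ran from -2.81 to 0.07. At 20 pg/mL no other gene passed. At 200 pg/mL 3 genes rose and 1 fell. Besides Ifng these were Il18rap (0.83 ± 0.15), Fasl (chromosome 1, 161780689 to 161788495), which encodes the death ligand of cytotoxic lymphocytes (1.40 ± 0.26), and the nuclear receptor gene Esrra (chromosome 19, 6910977 to 6921813) (-0.64 ± 0.13). At 2000 pg/mL 6 rose and 0 fell. Besides Ifng these were Il18rap (0.99 ± 0.15), the other IL-18 receptor chain gene Il18r1 (chromosome 1, 40465552 to 40500854) (1.11 ± 0.22), the granzyme gene Gzma (chromosome 13, 113093825 to 113100981) (1.79 ± 0.29), the chemokine gene Xcl1 (chromosome 1, 164931644 to 164935527) (2.39 ± 0.47) and Fasl (1.30 ± 0.26), the last chosen after its values were seen. Tbx21 did not pass at any dose (0.77 ± 0.17 at 2000 pg/mL, adjusted p = 0.26). Markers of T and NK cells were present in the 4 h controls, with the T cell receptor gene Cd3e at 3.84 ± 0.25 and the cytotoxic granule gene Nkg7 at 3.52 ± 0.19.

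Among type 1 lymphocyte genes, 1 rose, 0 fell and 23 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.2 up) at 20 pg/mL. At 200 pg/mL, 2 rose, 0 fell and 22 did not pass (7 and 1 adjusted over the list alone, camera adjusted p = 3.5e-09 up, adjusted p = 0.13 with an estimated correlation). At 2000 pg/mL, 4 rose, 0 fell and 20 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 5.9e-15 up). Of NK cell genes at 2000 pg/mL, 1 rose, 0 fell and 9 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.0063 up, adjusted p = 0.64 with an estimated correlation), and of T cell genes, none of 13 passed (0 and 0 adjusted over the list alone, camera adjusted p = 0.55 up). Of interferon signalling genes at 2000 pg/mL, none of 19 passed (0 and 0 adjusted over the list alone, camera adjusted p = 0.0063 up, adjusted p = 0.64 with an estimated correlation), and of the GTPases, none of 17 passed (0 and 0 adjusted over the list alone, camera adjusted p = 0.056 up). At an unadjusted p under 0.05, limma gave 863, 717 and 410 genes at 20, 200 and 2000 pg/mL. If no gene changed, a share of 0.05 of the 10183 tested genes would lie under that p on average, which the last count does not reach. Counts of this kind are therefore no evidence of weaker responses by themselves. At 20 pg/mL the log2 differences also ran with transcript length (Spearman's rho -0.21).

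The Ifng calls rest on the spread shared by all 4 h libraries. With the 6 compared libraries alone, limma gave Ifng adjusted p of 0.87, 0.39 and 0.66 at the 3 doses. Leaving out 1 library moved the counts. At 20 pg/mL the count of 1 became 3, 2 and 3 without replicates 1, 2 and 3 of the IL-12 group. At 200 pg/mL the count of 4 became 1 without replicate 1 of the IL-12 group, and 1, 2 and 1 without replicates 1, 2 and 3 of the control. Il18rap was lost without replicates 1 (adjusted p = 0.12) and 3 (0.13) of the IL-12 group and 1 (0.053) and 3 (0.15) of the control, Fasl without these (0.13, 0.15, 0.057, 0.12) and control 2 (0.19), and Esrra without any 1 of the 6 (0.11 to 0.26). At 2000 pg/mL the count of 6 became 2 without replicate 1 or 3 of the IL-12 group, and 2 and 3 without replicates 2 and 3 of the control. Il18rap passed without each of the 6, whereas Gzma was lost without replicates 1 (0.065) and 3 (0.1) of the IL-12 group and control 2 (0.12). Il18r1 was lost without any 1 (0.097 to 0.45) but control 1, and Xcl1 (0.067 to 0.45) and Fasl (0.082 to 0.52) without any 1 of the 6. With mouse number as a replicate block, a paired fit, Esrra (0.073) and, at 2000 pg/mL, Il18r1 (0.051) and Fasl (0.051) did not pass.

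The same doses of IL-12 were also compared in the presence of IFNγ at 0.5 ng/mL. Ifng stood at -0.82 ± 1.11 with IFNγ alone, and at 3.71 ± 0.55, 5.08 ± 0.46 and 5.29 ± 0.38 with 20, 200 and 2000 pg/mL of IL-12. The log2 differences were 4.53 ± 0.55 (adjusted p = 0.00075), 5.90 ± 0.55 (9.5e-06) and 6.11 ± 0.55 (5.1e-06). At 20 pg/mL no other gene passed. At 200 pg/mL Xcl1 (2.63 ± 0.47) and Mfge8 (chromosome 7, 79133768 to 79149060), which encodes a phosphatidylserine-binding protein (0.69 ± 0.14), rose too. At 2000 pg/mL Xcl1 did (2.81 ± 0.47). No gene fell, and limma gave 272, 482 and 549 genes at an unadjusted p under 0.05. For type 1 lymphocyte genes at 2000 pg/mL, 2 rose, 0 fell and 22 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 1.7e-05 up, adjusted p = 0.52 with an estimated correlation).

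With the compared groups alone, Ifng had adjusted p of 1, 0.26 and 0.15 at the 3 doses given with IFNγ. The count at 200 pg/mL fell from 3 to 1 without any 1 of its 6 libraries, where Xcl1 had adjusted p from 0.068 to 0.62. The count at 2000 pg/mL fell from 2 to 1 without replicate 1, 2 or 3 of the IL-12 group or replicate 1 or 2 of its control, where Xcl1 had 0.12, 0.084, 0.15, 0.092 and 0.2. Mfge8 had an adjusted p of 0.1 with the replicate block.

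Whether IFNγ changed the effect of IL-12 at 4 h was tested at 2000 pg/mL as the difference between these effects. No gene passed in limma, 0 of 10183, with 247 at an unadjusted p under 0.05. Leaving out replicate 2 of the group with IL-12 alone gave 1. For Ifng the difference was -0.02 ± 0.78, with a 95% interval from -1.65 to 1.62. Of type 1 lymphocyte genes, none of 24 passed (0 and 2 adjusted over the list alone, camera adjusted p = 0.47 down).

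A further comparison, with IFNγ at 3 ng/mL for 4 h in both groups, set cultures with IL-12 left alone against cultures with IL-12 blocked, and so asks whether IL-12 made in the culture acts. Ifng did not pass (0.41 ± 0.55, adjusted p = 0.81), nor did Tbx21 (-0.06 ± 0.17), Il12rb1 (-0.35 ± 0.42) or Cxcl10 (-0.04 ± 0.38). Of the genes that passed, 21 rose, such as the scramblase gene Xkr8 (0.57 ± 0.12) and Nid1 (0.44 ± 0.10). The other 109 fell, such as the respiratory chain gene Ndufa3 (-0.42 ± 0.07, adjusted p = 0.012) and the mitochondrial ribosome gene Mrpl52 (-0.43 ± 0.09). The genes that fell had a median length of 618 nt, against 2189 nt for those that rose and 1334 nt for all tested. The blocked group is also the 3 ng/mL group of the dose comparison, where Xkr8 passed in the other direction (-0.59 ± 0.12). Xkr8 lay at 2.21 in that shared group, 2.78 with IL-12 left alone and 2.80 with IFNγ at 0.5 ng/mL. Nid1 lay at 3.07, 3.51 and 3.39. Such calls may come in part from the values of the shared group, which was not tested. Among type 1 lymphocyte genes, none of 24 passed (0 and 0 adjusted over the list alone, camera adjusted p = 0.93 up).

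The count of 130 was 0 without replicate 1 or 3 of the blocked group (1156 and 1154 genes at an unadjusted p under 0.05 in limma) and without replicate 1 or 3 of the group left alone (948 and 1403). It was 546 without replicate 2 of the latter, 0 (973 unadjusted) with the 6 libraries fitted alone, and 78 with mouse number as a replicate block. Xkr8, Nid1, Ndufa3 and Mrpl52 were lost wherever the count is 0.

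At 24 h, IFNγ at 0.5 ng/mL with IL-12 blocked again raised Tbx21 (4.32 ± 0.10, adjusted p = 9.4e-17), Iigp1 (6.82 ± 0.29), Tgtp1 (6.23 ± 0.17), Serpina3f (6.07 ± 0.14), Irf1 (2.19 ± 0.09) and Socs1 (1.84 ± 0.12). The chemokine receptor gene Cxcr3, a target of T-bet, rose by 3.46 ± 0.23, Il12rb1 by 2.41 ± 0.17 and Stat4, the transducer of the IL-12 signal, by 1.11 ± 0.11. Also higher were Irg1, which encodes the enzyme that makes itaconate (2.79 ± 0.11), Mnda (2.65 ± 0.22), Cd86 (0.99 ± 0.08), Fas (1.26 ± 0.13), Cd274 (0.78 ± 0.09) and the glucose transporter gene Slc2a3 (0.88 ± 0.12). Prdm1 fell (-0.66 ± 0.13, adjusted p = 0.0026), as did Cr2 (-0.95 ± 0.09), the low-affinity IgE receptor gene Fcer2a (chromosome 8, 3681737 to 3694175) (-0.70 ± 0.11), the carbonic anhydrase gene Car2 (-0.93 ± 0.11), Hdac9 (-0.87 ± 0.10) and the TGFβ-presenting gene Lrrc32 (-1.06 ± 0.15). In total 472 genes rose and 275 fell of 10236. Bcl6 (0.13 ± 0.11), Pax5 (0.34 ± 0.14), Myc (0.10 ± 0.05) and Xbp1 (-0.07 ± 0.07) did not pass. The total of 747 became 430 without replicate 2 of the IFNγ group and 373 without replicate 1 of the control.

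By list at 24 h, 15 rose, 0 fell and 1 did not pass (15 and 0 adjusted over the list alone, camera adjusted p = 6.6e-35 up) among the GTPases. Of class I genes, 15 rose, 0 fell and 2 did not pass (15 and 0 adjusted over the list alone, camera adjusted p = 2.1e-19 up). Of interferon signalling genes, 11 rose, 0 fell and 8 did not pass (13 and 0 adjusted over the list alone, camera adjusted p = 5.2e-12 up). Of type 1 lymphocyte genes, 9 rose, 0 fell and 7 did not pass (11 and 0 adjusted over the list alone, camera adjusted p = 9.6e-13 up). Of glycolysis genes, 3 rose, 0 fell and 16 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 3e-04 up, adjusted p = 0.2 with an estimated correlation). Of unfolded protein response genes, 0 rose, 5 fell and 19 did not pass (1 and 9 adjusted over the list alone, camera adjusted p = 0.0045 down, adjusted p = 0.34 with an estimated correlation). Of class II genes, 3 rose, 0 fell and 8 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.24 up). Of type I interferon genes, 2 rose, 1 fell and 23 did not pass (2 and 1 adjusted over the list alone, camera adjusted p = 0.9 down).

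IL-12 at 20 pg/mL for 24 h with IFNγ blocked raised 42 genes and lowered 0 (limma, 852 at an unadjusted p under 0.05). Those that rose include Serpina3f (2.87 ± 0.14, adjusted p = 1.7e-10), Iigp1 (3.12 ± 0.29), Tgtp1 (2.19 ± 0.17), Serpina3g (1.55 ± 0.10), Tbx21 (1.45 ± 0.10), Irf1 (1.18 ± 0.09), Irg1 (0.99 ± 0.11) and Gbp2 (0.70 ± 0.08). Stat4 (0.30 ± 0.11), Cxcr3 (0.48 ± 0.23), Cxcl10 (0.40 ± 0.16), Prdm1 (-0.30 ± 0.13) and Bcl6 (-0.02 ± 0.11) did not pass. Ifng lay under the expression filter at 24 h, with a level of -3.54 ± 0.44 with both blocked, -1.68 ± 2.20 with IL-12, -3.10 ± 0.75 with IFNγ and -1.70 ± 0.19 with both. Of the GTPases, 8 rose, 0 fell and 8 did not pass (13 and 0 adjusted over the list alone, camera adjusted p = 1.5e-23 up). Of class I genes, 1 rose, 0 fell and 16 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 1.7e-07 up). Of interferon signalling genes, 2 rose, 0 fell and 17 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 6.3e-07 up, adjusted p = 0.086 with an estimated correlation). Of mitosis genes, none of 20 passed (0 and 0 adjusted over the list alone, camera adjusted p = 0.0031 down, adjusted p = 0.41 with an estimated correlation).

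Of the 42 genes that rose with IL-12 at 24 h, 33 also rose with IFNγ at 24 h, where 1.94 would be shared if the lists were independent, and 0 fell. Both comparisons use the same 3 control libraries, so part of the excess may come from these. Across all tested genes the log2 differences of the 2 comparisons had a correlation of 0.65 and a covariance of 0.0342, against means of 0.5 and 0.0101 in 100 simulated draws of unchanged genes with the same shared controls. Without replicates 1 and 2 of the IL-12 group the 42 genes became 25 and 15, and without replicates 1 and 3 of the control 25 and 16. The 33 shared genes became 21, 15, 20 and 15 without these libraries.

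Added to IFNγ for 24 h, IL-12 at 20 pg/mL raised 207 genes and lowered 119. Relative to IFNγ alone, Tbx21 rose by a further 2.11 ± 0.10 (adjusted p = 7.8e-11), Gbp4 by 1.67 ± 0.09, Socs1 by 1.91 ± 0.12, Cxcl10 by 1.88 ± 0.16, Iigp1 by 2.77 ± 0.29, the peroxisomal membrane gene Pxmp2 by 1.77 ± 0.13 and Il12rb1 by 1.30 ± 0.17. Cd274 rose by 0.94 ± 0.09, Irf8 by 0.84 ± 0.06, Stat4 by 0.64 ± 0.11 and Fas by 1.06 ± 0.13. Fcer2a (-1.54 ± 0.11, adjusted p = 1.9e-08), the chemokine gene Ccl22 (-1.21 ± 0.09), Car2 (-1.04 ± 0.11), the cytokine receptor gene Flt3 (-0.85 ± 0.10), the homing integrin gene Itgb7 (-0.84 ± 0.14), Cr2 (-0.74 ± 0.09), Cd24a (-0.61 ± 0.05) and the transcriptional inhibitor gene Id3 (-0.67 ± 0.07) fell. Of the GTPases, 15 rose, 0 fell and 1 did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 3.1e-41 up). Of class II genes, 0 rose, 3 fell and 8 did not pass (0 and 5 adjusted over the list alone, camera adjusted p = 2e-04 down, adjusted p = 0.17 with an estimated correlation). Of B cell identity genes, 0 rose, 5 fell and 15 did not pass (0 and 8 adjusted over the list alone, camera adjusted p = 0.00059 down, adjusted p = 0.31 with an estimated correlation). Of cell death genes, 2 rose, 1 fell and 17 did not pass (3 and 1 adjusted over the list alone, camera adjusted p = 0.0064 up, adjusted p = 0.24 with an estimated correlation). The total of 326 became 212 without replicate 3 of the group with IFNγ alone.

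The effect of IL-12 at 24 h differed with and without IFNγ for 53 genes by the test of that difference, 25 with a higher and 28 with a lower effect in the presence of IFNγ. IFNγ made in the culture was blocked only where none was added, and the design cannot tell its part from that of the added IFNγ. The difference was 1.32 ± 0.12 for Gbp4 (adjusted p = 2.4e-05), 1.69 ± 0.19 for Pxmp2, 1.47 ± 0.22 for Cxcl10, 1.23 ± 0.17 for Socs1, 1.07 ± 0.13 for the GTPase gene Igtp, 0.78 ± 0.11 for the hypoxia response gene Hif1a and 0.63 ± 0.09 for Irf8. It was -1.56 ± 0.15 for Fcer2a (adjusted p = 2.4e-05), -1.32 ± 0.20 for Itgb7, -1.24 ± 0.13 for Ccl22, -0.94 ± 0.14 for Flt3, -0.62 ± 0.11 for Id3 and -0.39 ± 0.07 for H2-Aa. For Tbx21 it was 0.66 ± 0.13 (adjusted p = 0.027). Irf1 (-0.15 ± 0.13) and Il12rb1 (0.50 ± 0.24) did not pass. With a rise standing for a higher effect beside IFNγ, 7 rose, 0 fell and 9 did not pass (14 and 0 adjusted over the list alone, camera adjusted p = 2.2e-19 up, adjusted p = 0.052 with an estimated correlation) among the GTPases. Of class II genes, 0 rose, 2 fell and 9 did not pass (0 and 6 adjusted over the list alone, camera adjusted p = 2.8e-07 down, adjusted p = 0.14 with an estimated correlation). Of B cell identity genes, 0 rose, 3 fell and 17 did not pass (0 and 8 adjusted over the list alone, camera adjusted p = 7e-06 down, adjusted p = 0.28 with an estimated correlation). Of trafficking genes, 0 rose, 3 fell and 11 did not pass (1 and 4 adjusted over the list alone, camera adjusted p = 0.004 down, adjusted p = 0.28 with an estimated correlation).

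The 53 genes became 34 without replicate 1 of the group with both cytokines blocked, 80 with the replicate block and 21 without the trend and robust settings of limma, where Cxcl10 (0.053), Irf8 (0.053), H2-Aa (0.12) and Tbx21 (0.076) did not pass. Tbx21 had adjusted p of 0.099 and 0.097 without replicates 1 and 2 of the group with both cytokines, 0.075 and 0.062 without those of IL-12 alone, 0.052 and 0.068 without those of IFNγ alone and 0.086 without replicate 1 of both blocked.

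Together for 24 h, against both blocked, the cytokines raised 1310 genes and lowered 1626, 198 and 75 of them by a log2 difference of 1 or more. Tbx21 rose 86.2-fold (6.43 ± 0.10, adjusted p = 9.6e-20), Iigp1 by 9.58 ± 0.29, Tgtp1 by 8.46 ± 0.17, Serpina3f by 8.11 ± 0.14, Cxcr3 by 4.38 ± 0.23, Socs1 by 3.75 ± 0.12 and Il12rb1 by 3.71 ± 0.17. Cxcl10 rose by 3.26 ± 0.16, Irf1 by 3.22 ± 0.09, Stat4 by 1.75 ± 0.11, Cd86 by 1.59 ± 0.08 and Bcl6 by 0.49 ± 0.11. Fcer2a (-2.25 ± 0.11), Car2 (-1.97 ± 0.11), Cr2 (-1.69 ± 0.09), Hdac9 (-1.65 ± 0.10), Ccl22 (-1.63 ± 0.09), the pseudokinase gene Trib2 (-1.55 ± 0.13), Flt3 (-1.50 ± 0.10), Prdm1 (-0.59 ± 0.13) and Irf4 (-0.49 ± 0.09) fell. Of the GTPases, 16 rose, 0 fell and 0 did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 4.3e-30 up). Of class I genes, 15 rose, 0 fell and 2 did not pass (15 and 0 adjusted over the list alone, camera adjusted p = 1.1e-14 up). Of type 1 lymphocyte genes, 10 rose, 0 fell and 6 did not pass (11 and 0 adjusted over the list alone, camera adjusted p = 3.5e-10 up). Of cell death genes, 8 rose, 2 fell and 10 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 0.0011 up, adjusted p = 0.15 with an estimated correlation). Of plasma cell genes, 4 rose, 10 fell and 5 did not pass (4 and 10 adjusted over the list alone, camera adjusted p = 0.35 down). The share of called genes that rose, 44.6%, became 55.6% (1526 up and 1219 down) when a trend with transcript length was removed from each library, an alternative chosen after seeing the data.

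Time in culture with LPS, 24 h against 4 h with both cytokines blocked, changed most genes: 3783 rose and 4514 fell of 10187. Since the values have nearly the same distribution in every library, these changes are relative to the other genes. They do not show changes in the amount of RNA per cell. Among the genes that rose most were the ankyrin repeat gene Ankrd37 (6.61 ± 0.15), the lactate transporter gene Slc16a3 (6.32 ± 0.18), Aldoc (5.84 ± 0.15) and the mitophagy gene Bnip3 (5.57 ± 0.11). Genes of DNA replication rose, such as Cdc6 (4.99 ± 0.13), Rrm2 (4.54 ± 0.10) and Tyms (4.24 ± 0.11). Prdm1 (2.38 ± 0.13), Il12rb1 (3.95 ± 0.38), Bach2 (2.20 ± 0.09) and Xbp1 (0.50 ± 0.07) rose. Bcl6 (-1.59 ± 0.09), Pax5 (-1.78 ± 0.12), Irf4 (-1.91 ± 0.07), Myc (-1.41 ± 0.06), Cd86 (-3.12 ± 0.06), the activation marker gene Cd83 (-2.53 ± 0.04), the survival gene Bcl2l1 (-3.51 ± 0.06), Fcer2a (-4.53 ± 0.10), Stat4 (-2.15 ± 0.09), Il12rb2 (-2.05 ± 0.30) and Cxcl10 (-4.00 ± 0.34) fell. Tbx21 did not pass (-0.02 ± 0.15).

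By list over time, 24 rose, 0 fell and 0 did not pass (24 and 0 adjusted over the list alone, camera adjusted p = 1.1e-13 up) in the S phase list. Of mitosis genes, 19 rose, 0 fell and 0 did not pass (19 and 0 adjusted over the list alone, camera adjusted p = 4.1e-09 up). Of glycolysis genes, 19 rose, 0 fell and 0 did not pass (19 and 0 adjusted over the list alone, camera adjusted p = 2.6e-11 up). Of NF-kappaB targets, 1 rose, 20 fell and 0 did not pass (1 and 20 adjusted over the list alone, camera adjusted p = 9e-09 down). Of ribosome biogenesis genes, 1 rose, 19 fell and 0 did not pass (1 and 19 adjusted over the list alone, camera adjusted p = 0.00031 down, adjusted p = 0.2 with an estimated correlation). Of activation genes, 3 rose, 14 fell and 1 did not pass (3 and 14 adjusted over the list alone, camera adjusted p = 0.0022 down, adjusted p = 0.087 with an estimated correlation). Of B cell identity genes, 3 rose, 15 fell and 2 did not pass (3 and 15 adjusted over the list alone, camera adjusted p = 0.0025 down, adjusted p = 0.26 with an estimated correlation). Of unfolded protein response genes, 15 rose, 9 fell and 0 did not pass (15 and 9 adjusted over the list alone, camera adjusted p = 0.015 up, adjusted p = 0.26 with an estimated correlation).

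Markers of T and NK cells fell over the same time. Of T cell genes, 0 rose, 12 fell and 0 did not pass (0 and 12 adjusted over the list alone, camera adjusted p = 2.5e-05 down, adjusted p = 0.087 with an estimated correlation). Of NK cell genes, 0 rose, 8 fell and 0 did not pass (0 and 8 adjusted over the list alone, camera adjusted p = 0.00039 down, adjusted p = 0.087 with an estimated correlation). Of myeloid genes, 1 rose, 4 fell and 1 did not pass (1 and 4 adjusted over the list alone, camera adjusted p = 0.19 down). Of dendritic cell genes, 3 rose, 3 fell and 1 did not pass (3 and 3 adjusted over the list alone, camera adjusted p = 0.61 down), with a rise of Flt3 (1.47 ± 0.09). The erythroid gene Car2 rose (0.29 ± 0.09, adjusted p = 0.0049) but did not pass with the replicate block (adjusted p = 0.19) or with the length trend removed (0.083). Cd3e went from 3.84 ± 0.25 to -3.54 ± 0.24, which is the lowest mean any gene has in that group. Other genes share that mean, Klrd1, Ifng, Fasl, Gzma and Xcl1 among them, so it may be a floor. The size of falls that end there is then uncertain, and SDs and p-values at that level may not reflect the spread of expression. The NK cell receptor gene Klrd1 went from 2.37 ± 0.09 to -3.54 ± 0.24, Nkg7 from 3.52 ± 0.19 to -2.74 ± 0.73 and the macrophage gene Lyz2 from 3.12 ± 0.32 to -2.62 ± 0.62. Ifng, at -1.22 ± 1.46 and -3.54 ± 0.44, had an adjusted p of 0.0032, and of 0.11 with the replicate block.

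The joint effect of IL-12 at 20 pg/mL and IFNγ at 0.5 ng/mL differed between 24 h and 4 h for 2964 genes by the test of that difference. It was higher at 24 h for 1325 genes, such as Cxcr3 (4.40 ± 0.30, adjusted p = 5.1e-15), the chromatin organiser gene Satb1 (2.47 ± 0.13), the glycosyltransferase gene B3gnt7 (2.43 ± 0.13), Stat4 (1.69 ± 0.12), the transcription factor gene Runx3 (1.44 ± 0.16), the decoy receptor gene Il1r2 (2.16 ± 0.20) and Cd86 (0.88 ± 0.09). It was lower for 1639, such as Gbp2 (-2.49 ± 0.13, adjusted p = 2.5e-16), Gbp3 (-1.58 ± 0.11), Serpinb1a (-2.40 ± 0.14), Car2 (-1.99 ± 0.13), Prdm1 (-1.29 ± 0.19), Psmb9 (-1.66 ± 0.18) and Irf8 (-0.31 ± 0.07). Tbx21 (-0.35 ± 0.21), Irf1 (0.16 ± 0.22), Socs1 (0.01 ± 0.37) and Il12rb1 (-0.21 ± 0.54) did not pass. With a rise standing for a higher effect at 24 h, 8 rose, 1 fell and 10 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 0.011 up, adjusted p = 0.78 with an estimated correlation) among glycolysis genes. Of type 1 lymphocyte genes, 9 rose, 1 fell and 12 did not pass (9 and 2 adjusted over the list alone, camera adjusted p = 0.025 up, adjusted p = 0.78 with an estimated correlation). Of class I genes, 2 rose, 8 fell and 6 did not pass (2 and 8 adjusted over the list alone, camera adjusted p = 0.27 down).

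**Figure D1:**
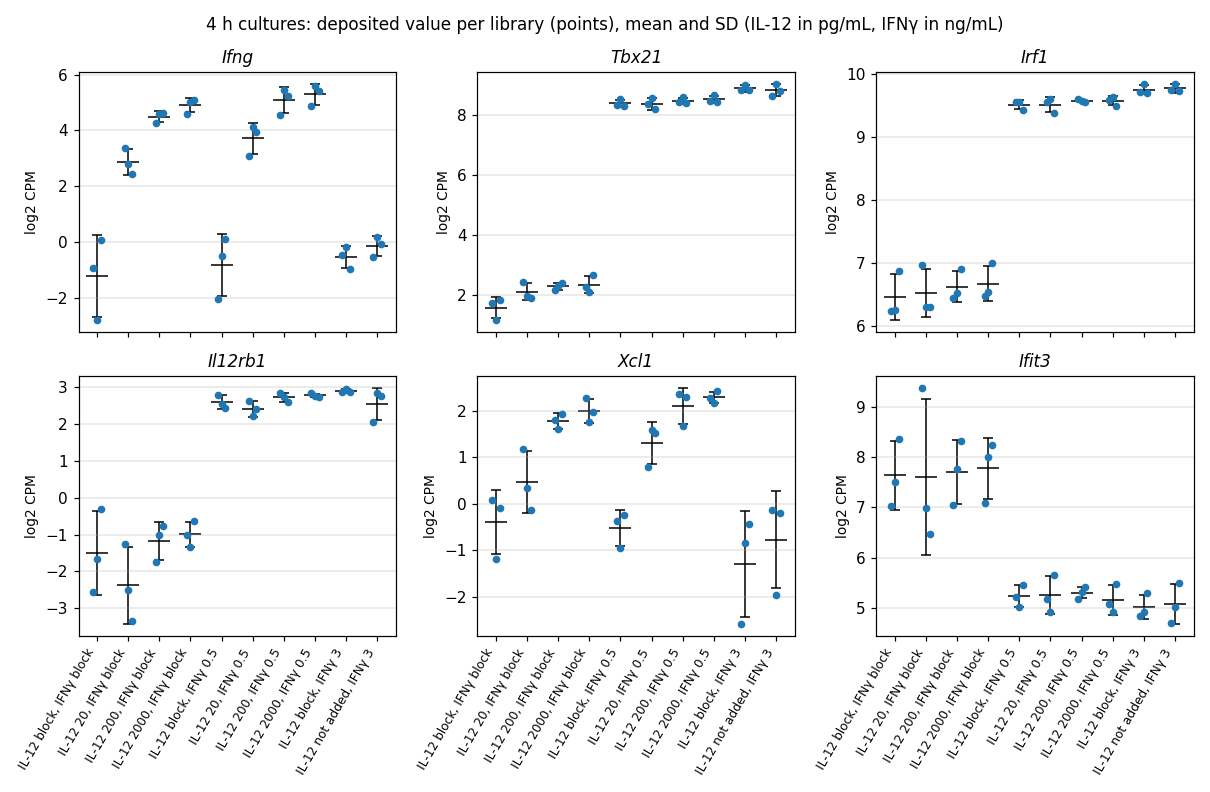
Log2 CPM of 6 genes in the 10 groups at 4 h, with a point per library and a bar for the mean and SD of 3 libraries. Ifng lies at -1.22 with both cytokines blocked and at 4.90 with 2000 pg/mL of IL-12, while Tbx21 lies at 1.58 with both blocked and at 8.38 with IFNγ at 0.5 ng/mL.

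**Figure D2:**
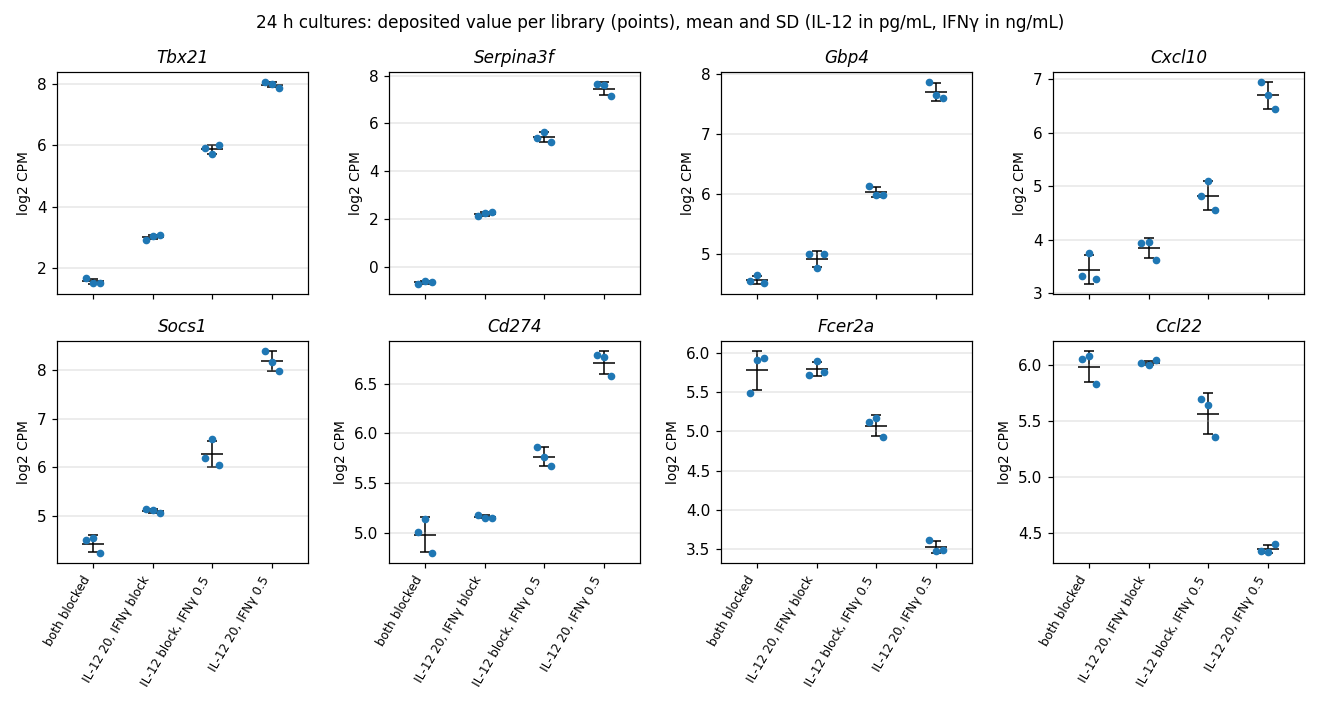
Log2 CPM of 8 genes in the 4 groups at 24 h, with a point per library and a bar for the mean and SD of 3 libraries. Tbx21 goes from 1.55 with both blocked to 3.00 with IL-12, 5.88 with IFNγ and 7.98 with both, and Fcer2a goes from 5.77 to 3.53 with both.

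**Figure D3:**
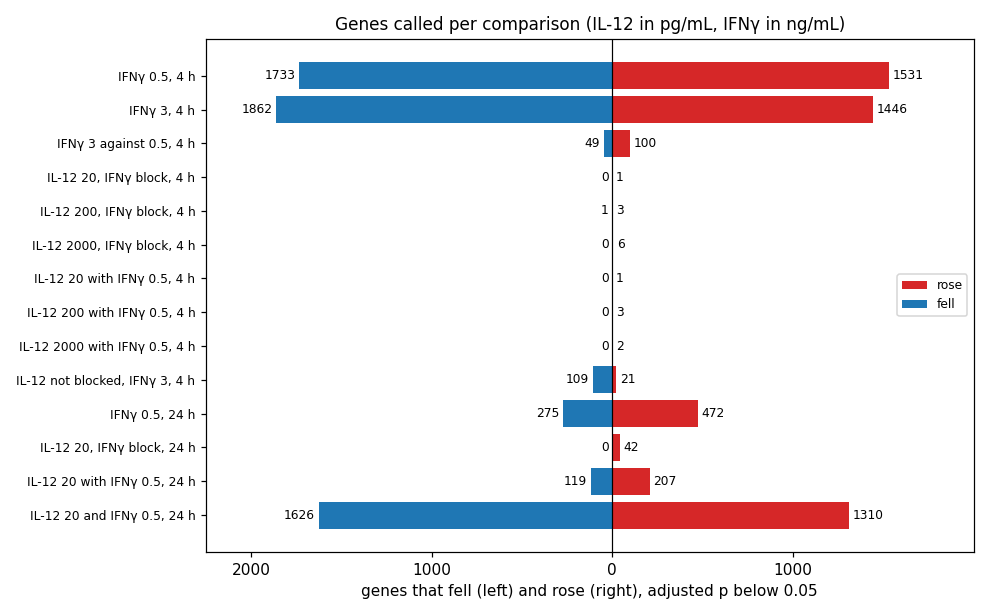
Number of genes that rose (to the right) and fell (to the left) at an adjusted p below 0.05 in limma for each comparison of 3 with 3 libraries within a time point. The counts with IFNγ at 0.5 ng/mL at 4 h are 1531 and 1733, against 6 and 0 with IL-12 at 2000 pg/mL.

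**Figure D4:**
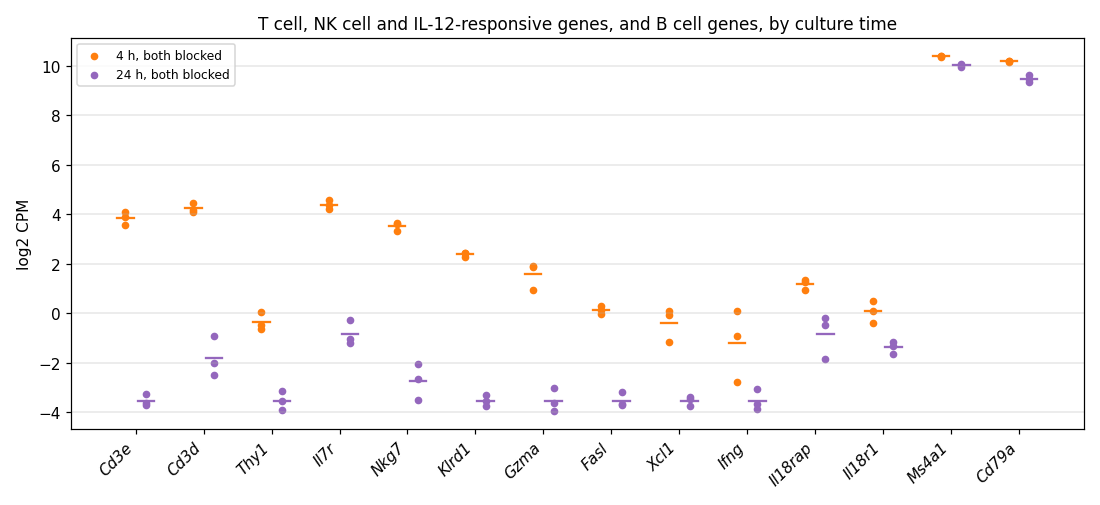
Log2 CPM of T cell, NK cell, IL-12-responsive and B cell genes with both cytokines blocked, with a point per library and a line for the mean of 3, at 4 h (orange) and 24 h (purple). Cd3e goes from 3.84 to -3.54.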

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

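The results here were picked out because the effect of a cytokine differed between 2 conditions by a test of that difference (limma). No test in this part was chosen after the result was seen.

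The effect of IL-12 at 24 h differed with and without IFNγ for 53 genes, where IFNγ made in the culture was blocked only if none was added. Mean log2 differences of the lists that passed camera were 0.61 for the GTPases, 0.2 for interferon signalling, -0.31 for type I interferon genes, -0.26 for MHC class II, -0.25 for B cell identity, -0.31 for trafficking, 0.09 for S phase and 0.12 for mitosis, and none of these held with an estimated correlation (adjusted p from 0.052 to 0.74). Among named genes the log2 difference was 1.69 for Pxmp2, 1.47 for Cxcl10, 1.32 for Gbp4, 1.23 for Socs1, 1.07 for Igtp, 0.78 for Hif1a, 0.66 for Tbx21 and 0.63 for Irf8. It was -1.56 for Fcer2a, -1.32 for Itgb7, -1.24 for Ccl22, -0.94 for Flt3, -0.62 for Id3 and -0.39 for H2-Aa. Of 40 drawn splits of these 12 libraries (the real one included, and each other one after removal of the separate cytokine effects), 2 called as many genes, the real one with 53 and another with 103, so chance is not excluded.

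The joint effect of IL-12 and IFNγ differed between 24 h and 4 h for 2964 genes, with mean log2 differences of 0.36 for type 1 lymphocyte genes and 0.28 for glycolysis, neither of which held with an estimated correlation (adjusted p = 0.78 for both). The log2 difference was 4.40 for Cxcr3, 2.47 for Satb1, 2.43 for B3gnt7, 2.16 for Il1r2, 1.69 for Stat4, 1.44 for Runx3 and 0.88 for Cd86. It was -2.49 for Gbp2, -2.40 for Serpinb1a, -1.99 for Car2, -1.66 for Psmb9, -1.58 for Gbp3, -1.29 for Prdm1 and -0.31 for Irf8. Of 40 splits drawn in the same way, 1 called as many genes, the real one with 2964, and the highest other called 1632. A share of 1 in 40 is the lowest these draws can give, and the regrouped values still held the tested difference. The draws make chance less likely but do not exclude it. Markers of T and NK cells fell over the same time, and no explanation of these differences other than chance was tested.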

How the results depend on the processing

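Settings that left out a whole group or removed a trend with transcript length were chosen after seeing the data, and the others before. Of 3224 repeats of the values of named genes under another setting, 3100 kept their direction and their side of the threshold, 115 missed the threshold, 2 passed it and none of the called ones turned its direction, while 7 that were never called changed sign by more than their standard error. Removing the length trend turned the sign of 288 genes called between 4 h and 24 h. Quantile normalization and testing all genes without a filter kept every count within 1.5 times. Where a count moved, the cause was not tested, apart from stricter thresholds, which call fewer genes by construction. At an adjusted p under 0.01 the counts were 25 for IFNγ 3 against 0.5 ng/mL, 1 and 3 for IL-12 200 and 2000, 1 and 1 for IL-12 200 and 2000 with IFNγ, and 0 for IL-12 left alone (1471 at an unadjusted p under 0.05 in limma). At 24 h they were 345 for IFNγ, 17 for IL-12, 172 for IL-12 with IFNγ, 1656 for both and 30 for their interaction, with 16 shared genes, and 1885 for the difference between times. With a log2 difference of 1 or more they were 303 and 372 for IFNγ 0.5 and 3, 3 for the doses compared, 2 for IL-12 200 and 1 for IL-12 left alone at 4 h. At 24 h they were 82 for IFNγ, 8 for IL-12, 46 for IL-12 with IFNγ, 273 for both and 15 for their interaction, with 7 shared genes, then 3145 for time and 319 for the difference between times. Without the trend and robust settings of limma they were 60 for IFNγ 3 against 0.5, 2 for IL-12 20, 1 for IL-12 200 with IFNγ, 6 for IL-12 left alone, 11 for IL-12 at 24 h, 21 for the interaction at 24 h and 9 for shared genes. With only the compared groups fitted they were 707 for IFNγ 3 against 0.5, 0 for IL-12 20 (573 unadjusted), 1 for IL-12 200, which is not among the 4, 11 for IL-12 2000, 0 (384 unadjusted), 5 and 8 for IL-12 20, 200 and 2000 with IFNγ, 0 (973 unadjusted) for IL-12 left alone, and 83 for IL-12 at 24 h. With mouse number as a replicate block (paired) they were 78 for IL-12 left alone and 80 for the interaction at 24 h. Without the group with IL-12 20 and IFNγ blocked they were 227 for IFNγ 3 against 0.5 and 4 for IL-12 2000 with IFNγ, and without the group with IL-12 left alone 251 for IFNγ 3 against 0.5. Of 417 list tests 101 passed, 24 with an estimated correlation and 105 with the replicate block.

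Leaving out 1 library at a time gave 2647 to 3065 genes for IFNγ 0.5 at 4 h, 2842 to 2997 for IFNγ 3 and 21 to 154 for these doses compared. For IL-12 at 4 h it gave 1 to 3 (20), 1 to 3 (200) and 2 to 5 (2000), with IFNγ 1 to 1, 1 to 1 and 1 to 3, for the interaction 0 to 1 and for IL-12 left alone 0 to 546, where the 4 counts of 0 had 948 to 1403 genes at an unadjusted p under 0.05. At 24 h it gave 373 to 771 for IFNγ, 15 to 47 for IL-12, 212 to 331 for IL-12 with IFNγ, 2035 to 2653 for both, 34 to 70 for the interaction and 15 to 38 for shared genes. It gave 8038 to 8086 for time and 2435 to 2974 for the difference between times. The report names the libraries that moved a count by over 1.5 times. The comparisons of IL-12 20 and of IL-12 left alone could not be refitted without their own group. Another tool or pseudocount, planned for counts or linear values, was not run on log2 values. Depth per library is unknown, so what it limits was not examined.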

Other observations

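At 4 h IFNγ and IL-12 left different marks in these cultures. Over 4 h, IFNγ raised the T-bet gene Tbx21 together with GTPases, class I presentation genes, Socs1 and an IL-12 receptor chain, and lowered 6 of 11 class II and 13 of 20 B cell identity genes. Of all 10183 tested genes 1733 fell, and some members of these last lists rose. Their camera calls, and that of the GTPases, were lost with an estimated correlation. With IFNγ alone at 24 h no class II gene passed as lower. H2-Ab1 (-0.18 ± 0.06) came close in limma, with an adjusted p of 0.056, and of 0.035 with the replicate block. IL-12 over 4 h raised Ifng with few other genes. Over 24 h, IL-12 at 20 pg/mL with IFNγ blocked raised 42 genes, 33 of which IFNγ also raised. In the presence of IFNγ, IL-12 lowered Fcer2a, Ccl22 and Flt3, which IFNγ alone also lowered at 24 h (-0.70, -0.42 and -0.65). Prdm1 rose with IFNγ at 4 h and fell at 24 h, and the test of this difference for both cytokines gave -1.29.

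All tests of the next 3 patterns were chosen after the result was seen, except the test of IL-12 acting on some genes without IFNγ. The splits of the libraries were planned. Each explanation is a hypothesis tested on the data it came from.

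IL-12 raised Ifng and a few other genes at 4 h. B cells may answer in proportion to Il12rb1, which IFNγ raised by 4.10 (95% limits 3.24 and 4.95). The effect of 20 pg/mL on Ifng was larger beside IFNγ by only 0.45, with an upper 95% limit of 2.08, under the lower limit for Il12rb1. This does not decide the question, since Il12rb1 RNA was read at the end of the same 4 h. The receptor present while Ifng was induced is unknown, and the limits rest on the spread shared by all 4 h libraries. T or NK cells present in the 4 h cultures may answer to IL-12: 5 of the 8 genes called in any IL-12 comparison (Fasl, Gzma, Ifng, Il18rap, Xcl1) lay over 2 log2 units lower at 24 h than at 4 h with both cytokines blocked, against 468 of 10175 other genes (4.6%, Fisher's exact test p = 1.1e-05). Il18rap fell by 2.01, just past that limit, and Ifng by 2.32 (limma adjusted p = 0.11 with the replicate block). Fasl, Gzma, Ifng and Xcl1 ended at -3.54, the lowest mean of the 24 h group, which may be a floor, so the size of their falls is uncertain. The other genes were not matched for level, and Fisher's test takes genes as independent, so its p may be too small. All 12 tested T cell genes and all 8 NK cell genes fell over that time (another list also holds 1 and 4 of them), with Cd3e at 3.84, Nkg7 at 3.52 and Cd8a at 2.91 at 4 h, although the B cells had been purified, a step meant to remove such cells. Expression of these genes in B cells that fades with time stays open, since cell types were not separated, and of the 8 calls those of Ifng held without each compared library while most others did not (adjusted p of Gzma up to 0.12, of Xcl1 up to 0.62). With only the compared groups fitted, Ifng did not pass at any dose.

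IL-12 at 20 pg/mL with IFNγ blocked raised 42 genes at 24 h. IFNγ made in the culture and not fully blocked may account for most of them: 28 of the 42 also rose with IFNγ at 4 h, in other libraries, against 1448 of 9685 other genes (15%, Fisher's exact test p = 5.7e-14). The same overlap would arise if IL-12 acted on these genes without IFNγ, so it cannot tell these explanations apart. Fisher's test also takes genes as independent, which they are not. IL-12 acting on some genes without IFNγ may account for others: 8 of the 42 rose with IFNγ at neither time, although 4 of these 8 missed the threshold narrowly with IFNγ at 24 h, in the same direction (adjusted p from 0.058 to 0.074), and 1 of the 42 had a lower 95% limit above the upper 95% limit of the IFNγ effect at both times, which choosing the highest of 42 genes could also give. The count fell to 25 and 15 without replicates 1 and 2 of the IL-12 group and to 25 and 16 without replicates 1 and 3 of the control.

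IL-12 left alone, against blocked, lowered 109 genes at 4 h, with a median length of 618 nt against 1334 nt for all tested. IL-12 made in the culture at a level like 20 pg/mL is argued against by Ifng, whose difference had an upper 95% limit of 1.56, under the 4.09 seen with 20 pg/mL. A length bias between libraries may account for part or all of it and stays open: removing each library's trend with length gave 88 genes in place of 130, and 69 that fell in place of 109 (Spearman's rho of length and log2 difference across genes, which are not independent, is 0.24). The count was 0 without replicates 1 and 3 of either group (1156, 1154, 948 and 1403 genes at an unadjusted p under 0.05 in limma) and 546 without replicate 2 of the group left alone. An effect of blocking IL-12 on these genes stays open as well.

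Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. At 4 h the real and the highest other split called 3264 and 0 genes for IFNγ 0.5, 3308 and 0 for IFNγ 3, 149 and 0 for these doses compared, and 130 and 0 for IL-12 left alone. With IL-12 at 200 and 2000 pg/mL they called 4 and 2, and 6 and 1, and beside IFNγ at 20, 200 and 2000 pg/mL 1 and 0, 3 and 0, and 2 and 0. At 24 h they called 747 and 0 for IFNγ, 42 and 21 for IL-12, 326 and 0 for IL-12 beside IFNγ and 2936 and 0 for both, and for time 8297 and 0. In each of these 1 split called as many genes, the real one. For IL-12 at 20 pg/mL at 4 h, 3 of 10 splits called as many as the real 1, up to 195, for a reason that was not tested. That split parted the 3 mouse pairs as the real one does, and those that did not called at most 3. For IL-12 at 200 pg/mL at 4 h and at 20 pg/mL at 24 h the highest other split was one that kept mouse pairs together, with 0 as the highest of those that parted the 3. The interaction at 4 h called 0 genes (247 at an unadjusted p under 0.05 in limma), a count that all 40 drawn splits reach whatever the data, so these decide nothing.

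In 13 of the 14 groups the order of the sample number in the library names (S and a number) follows the mouse number. The group with IL-12 20 pg/mL and IFNγ blocked at 4 h is the exception. Its residuals correlated with those of the same number in other groups at -0.63, -0.28 and -0.53, and its libraries 1 to 3 had Ifit3 at 9.37, 6.98, 6.47, against 7.02, 7.51, 8.36 in the group with both blocked. Whether the mouse numbers of these 3 libraries are right is not known. If they are wrong, the replicate-block fit, any removal of a mouse effect before deposit and the account of mouse pairs in the splits for IL-12 at 20 pg/mL at 4 h are all affected. The median SD per gene ran from 0.0795 to 0.123 across groups.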
